A study of Homo sapiens with 8 samples.

How the data were processed

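Total RNA of MRC5 fibroblasts was labelled with biotin and hybridised to single-colour short-oligonucleotide arrays of a pair of types, one for the 6 h samples and one with fewer probe sets for the 12 h samples. Samples were grouped by the treatment and time in their labels, giving 1 treated and 1 mock array at 6 h and 3 treated and 3 mock arrays at 12 h. The time label and the sample description give 12 h for the latter, although the treatment protocol in the labels names 6 h for every sample, and the time label was followed.

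The authors deposited 1 intensity per probe set and array on a linear scale, made with MAS5 per the submitters' processing notes. The version and settings are not given in the sources used here. The mean of each array's values without the lowest and highest 2% was between 500.1 and 500.5, so the arrays had been scaled to a common level. No detection calls or scanner files were used. Array medians lay between 143 and 165. For arrays, the number of arrays limits the precision.

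Log2 of the deposited intensity was computed without further scaling. Control probe sets were left out. At 12 h, probe sets whose mean log2 value was below the 40th percentile were left out (a signal of 93.9), which kept 5248 and removed 3498. At 6 h the limit was the 50th percentile. Gene names came from the platform annotation supplied with the values. They were compared with a RefSeq gene table of assembly GRCh38.p14, which changed none of them and was used for names only. At 12 h, 7840 of 8746 probe sets had 1 symbol, 388 several and 518 none. At 6 h, 19064 of 22215 had 1, 1043 several and 2108 none. Probe sets with several symbols or none were not named. No coordinates are given, since no genome build is named for the arrays.

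The 12 h groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene is from this fit. Gene lists, 26 with 701 genes, were tested with camera at a preset inter-gene correlation of 0.01, with 1 probe set per gene, the brightest, and Benjamini-Hochberg adjustment over the lists. Camera was repeated with an estimated correlation, and fry, which does not compare a list with other genes, was run beside it. At 6 h no test was made. Each list's median log2 ratio was set against 10000 random lists of the same size matched on mean log2 value in 20 bins, which describes these arrays only.

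Genes were named by a rule. At 12 h these were the 10 largest rises and the 10 largest falls among probe sets past the threshold with 1 symbol and no overlap between the groups. At 6 h they were the 10 highest and the 10 lowest ratios among probe sets with 1 symbol and a mean log2 value at or above the 60th percentile. Up to 4 members of each list with the largest changes, and OGG1, were added. The result of 1 gene list and of a group of control probe sets is not reported here. The groups, gene lists, main tests, the settings listed in the last paragraph and the naming rule were fixed before the data were examined. The limits of 1.5-fold and of a signal of 4000, the tests of scaling, RNA quality, culture and spike-ins, and the gene families were added after the results were seen.

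The 12 h test was tested on simulated data drawn from the real means and spreads of the 5248 probe sets with 200 changed. It recovered 84 of 100 changed by 2-fold and 45 of 100 changed by 1.5-fold, with 5 false calls. With 1 list shifted by 0.5 on the log2 scale over 4670 genes, camera called that list and 0 of the other 25. The simulated probe sets were drawn independently, without correlation between genes. The simulation therefore cannot show how often lists of correlated genes are called falsely.

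The alternatives were median centring, quantile normalization, no filter and a stricter filter on dim probe sets (60th percentile at 12 h and 70th at 6 h), a constant added before log2 (the 20th percentile of the signals), no intensity trend, the replicate number as a block, other list tests, the mean of a gene's probe sets, and leaving out each 12 h array in turn.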

Results

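MRC5 cells, human diploid lung fibroblasts, were exposed to 10 µM 8-oxoguanine, the free oxidised guanine base, or mock treated with its solvent. Total RNA was read on 8 expression arrays. At 6 h there was 1 array per treatment, and at 12 h there were 3 arrays per treatment, which the labels call technical replicates by extract. The 6 h arrays carried 22215 probe sets apart from controls and the 12 h arrays 8746, so the times were analysed apart. The question was how exposure to the base changes gene expression in these fibroblasts at each time. The number of arrays limits the precision of every value. Nothing in the labels says that the 12 h extracts came from separate cultures, so p-values measure only the spread between these extracts, which may be technical.

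At 12 h the largest fall was that of TXNIP, a glucose-responsive inhibitor of thioredoxin, whose signal was 1585 ± 139 (SD, n = 3) in mock cells and 154 ± 10.0 (SD, n = 3) in treated cells, a log2 fold change of -3.36 (SE 0.10). ID1 and ID3, inhibitors of DNA-binding helix-loop-helix factors, fell, with log2 fold changes of -2.09 (SE 0.08) and -2.23 (SE 0.11). TRIB3 and ASNS, a stress-induced pseudokinase and asparagine synthetase, rose by 1.52 (SE 0.09) and 1.35 (SE 0.07). Of the listed genes of mitosis and G2, 17 of 24 fell, and of those of DNA replication 10 of 19. OGG1, the glycosylase that removes 8-oxoguanine from DNA, had a log2 fold change of -0.08 (SE 0.21, limma adjusted p = 0.865), with a signal of 159 ± 16.4 in mock and 153 ± 36.7 in treated cells (SD, n = 3), and the sign of this change turned when 8-oxoguanine replicate 1 (0.14) or mock replicate 3 (0.0013) was left out.

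Of 5248 probe sets tested at 12 h, 695 passed the threshold in limma's moderated test, 346 higher and 349 lower in treated cells. They stood for 618 named genes, and 25 of the higher and 27 of the lower probe sets changed by 2-fold or more. The arrays of the groups did not overlap at 1778 probe sets, 33.9% of those tested, where chance gives 10%. Pairs of arrays of one treatment differed by 2-fold or more at 26 to 72 probe sets, and pairs across treatments at 101 to 163. The count fell to 371 without 8-oxoguanine replicate 1, to 386 without 8-oxoguanine replicate 2 and to 451 without mock replicate 3.

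Among the 10 largest rises, TRIB3, ASNS and NUPR1 (1.26, SE 0.09) encode stress-response products, and MME (1.51, SE 0.12) encodes the membrane protease neprilysin. CYP1B1, a cytochrome P450 enzyme, rose by 1.49 (SE 0.22) from a dim signal of 61.0 ± 8.73, GDF5, a secreted growth factor, by 1.44 (SE 0.21) from 114 ± 32.7 (SD, n = 3), and ADAMTS5, a matrix protease, by 1.30 (SE 0.13). KLF13 (1.61, SE 0.39), PSMB8 (1.42, SE 0.36) and CLCA2 (1.26, SE 0.33) were also dim in mock cells, with signals of 85.1 ± 43.0, 123 ± 69.2 and 116 ± 63.1 (SD, n = 3), and each lost its call when any one 8-oxoguanine array was left out. The other large falls were those of GINS2, a replication factor (-2.44, SE 0.38), MMP3, a stromal metalloproteinase (-2.11, SE 0.22), ANGPTL4 (-1.86, SE 0.32), EDN1, which encodes endothelin (-1.77, SE 0.20), SCG2 (-1.48, SE 0.25), NPTX1 (-1.40, SE 0.11) and ENDOG, a mitochondrial nuclease (-1.33, SE 0.24). In treated cells GINS2 (81.1 ± 41.7), MMP3 (75.6 ± 23.9), ANGPTL4 (68.3 ± 32.0), SCG2 (86.4 ± 25.8) and ENDOG (59.7 ± 9.27; SD, n = 3) had signals under the filter limit of 93.9, so the size of these falls is uncertain. The same holds for LIG1, DUSP4 and SMAD6 below (treated signals of 92.6, 79.9 and 80.4). The mock signals of CYP1B1 and KLF13 were also under this limit, so the size of their rises is uncertain too.

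**Figure D1:**
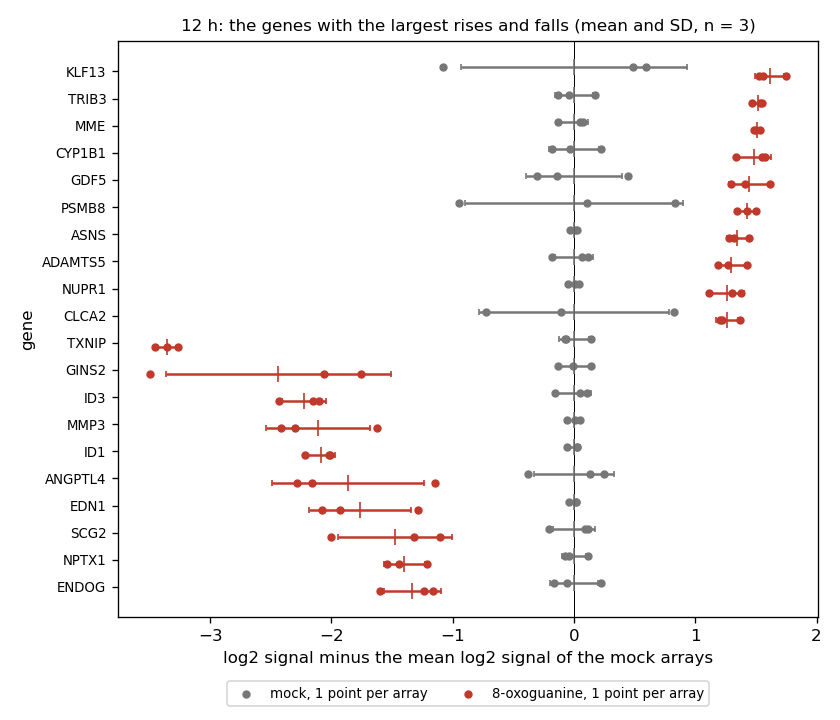
Each point is 1 array at 12 h, placed on the horizontal axis by its log2 signal minus the mean log2 signal of the 3 mock arrays, with 1 gene per line on the vertical axis and the mean and SD of each group (n = 3) as a tick and bar. TXNIP lies furthest below the mock arrays, at a log2 fold change of -3.36, and KLF13 furthest above, at 1.61, with a wide spread among its mock arrays.

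Cell cycle genes formed the clearest group at 12 h. Of 24 measured genes of mitosis and G2, 17 fell, none rose and 7 did not pass, and 20 fell when adjusted over the list alone. CCNA2, the cyclin of S and G2 phase, fell by 0.98 (SE 0.11), BIRC5, or survivin, by 0.93 (SE 0.13), and KIF11 and CENPE, mitotic kinesins, by 0.92 (SE 0.14) and 0.91 (SE 0.17). Of 19 genes of DNA replication and G1/S, 10 fell, none rose and 9 did not pass, and 12 fell when adjusted over the list alone. CDC6, a licensing factor, fell by 1.25 (SE 0.17), RRM2, a ribonucleotide reductase subunit, by 1.19 (SE 0.09), POLE2 by 0.97 (SE 0.26) and GMNN, or geminin, by 0.93 (SE 0.16). The lists' median log2 fold changes were -0.65 and -0.49, with camera adjusted p = 6.26e-13 and 1.36e-09. These were the lists whose call held with an estimated correlation between genes, with adjusted p = 0.0275 and 0.0280.

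In the list of the unfolded protein and integrated stress response, 10 of 19 measured genes rose, none fell and 9 did not pass, and 12 rose when adjusted over the list alone. TRIB3 and ASNS led, followed by PSAT1 (0.97, SE 0.06) and PHGDH (0.78, SE 0.10), enzymes of serine synthesis. The median was 0.30 (camera adjusted p = 2.65e-08), and the adjusted p was 0.142 with an estimated correlation. In a family of endoplasmic reticulum chaperones drawn after the results were seen, 3 of 8 fell (SDF2L1, MANF and HYOU1) and none rose. The rise of the list therefore did not extend to these chaperones. Of 23 genes of glycolysis and the hypoxia response, 14 fell, none rose and 9 did not pass, and 16 fell when adjusted over the list alone. ENO2, a neuronal-type enolase, fell by 1.22 (SE 0.12), BNIP3, a mitophagy receptor, by 0.84 (SE 0.07), PFKP, a phosphofructokinase, by 0.83 (SE 0.10) and NDRG1 by 0.59 (SE 0.10). Their median was -0.32 (camera adjusted p = 1.04e-08), and the adjusted p was 0.142 with an estimated correlation.

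Of 18 measured genes in the list of base excision repair and 8-oxoguanine handling, 4 fell, none rose and 14 did not pass, and 5 fell when adjusted over the list alone. The 4 were LIG1 (-0.94, SE 0.18), PCNA (-0.91, SE 0.14), UNG (-0.57, SE 0.16) and FEN1 (-0.49, SE 0.13), which also act at replication forks. The median was -0.13 (camera adjusted p = 0.0426), the adjusted p was 0.170 with an estimated correlation, and the call was also lost with the stricter filter (0.2999), without 8-oxoguanine replicate 1 (0.0869) and without mock replicate 3 (0.0576). Of 23 genes of purine synthesis and salvage, 6 fell, 1 rose and 16 did not pass, and 9 fell and 3 rose when adjusted over the list alone. DGUOK, a mitochondrial deoxyguanosine kinase, fell by 0.50 (SE 0.14), AMPD2 by 0.48 (SE 0.10), NME1 by 0.47 (SE 0.08) and PRPS1 by 0.42 (SE 0.09). The median was -0.14 (camera adjusted p = 0.0450), with adjusted p = 0.170 with an estimated correlation, and the call was lost with median centring (0.0582), quantile normalization (0.0569) and the stricter filter (0.0831). It was also lost without 8-oxoguanine replicate 1 (0.0579) or 3 (0.0894) or mock replicate 2 (0.0679) or 3 (0.0576).

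Of 18 TGF-beta response genes, 7 fell, 2 rose and 9 did not pass, with the same counts when adjusted over the list alone. Their median log2 fold change was -0.10 and their mean -0.32, so the largest falls weigh on the mean. ID1 and ID3 led, followed by SMAD6 (-1.14, SE 0.28) and SMAD7, the inhibitory SMADs, SMAD7 having a signal of 389 ± 7.19 in mock and 194 ± 6.12 in treated cells (SD, n = 3). Of 29 immediate early and RAS-MAPK feedback genes, 9 fell, 2 rose and 18 did not pass, and 10 fell and 3 rose when adjusted over the list alone. Their median was -0.15 and their mean -0.18. KLF10 fell by 1.01 (SE 0.17), IER3 by 0.84 (SE 0.10) and DUSP4, a MAP kinase phosphatase, by 0.83 (SE 0.21), while ATF3, a stress-induced factor, rose by 1.06 (SE 0.11). Both lists had camera adjusted p = 0.0450, adjusted p = 0.170 with an estimated correlation, and lost their call with median centring (0.0582 each) and quantile normalization (0.0569 each). The TGF-beta list also lost it with the stricter filter (0.0543) and without 8-oxoguanine replicate 3 (0.0565) or mock replicate 2 (0.0679). The immediate early list also lost it with the stricter filter (0.154) and without any one array but 8-oxoguanine replicate 2 (0.0505 to 0.123). Of 27 ribosomal protein genes, 3 rose, none fell and 24 did not pass, led by RPS25 (0.42, SE 0.12), RPS9 (0.36, SE 0.08) and RPL37 (0.31, SE 0.08), with 2 rising when adjusted over the list alone. Their median was 0.17 (camera adjusted p = 5.07e-05), and the adjusted p was 0.257 with an estimated correlation. Of 15 heat shock genes and chaperones, 3 fell, HSPE1 (-0.50, SE 0.11), HSPB1 (-0.32, SE 0.07) and CCT2 (-0.27, SE 0.07), and 12 did not pass, with 5 falling when adjusted over the list alone. Their median was -0.17 (camera adjusted p = 0.0232), and the adjusted p was 0.170 with an estimated correlation.

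The other 16 lists did not pass in camera's test at 12 h. Of 16 p53 target genes, 5 rose and 1 fell, with PLK2 at 0.87 (SE 0.10), ZMAT3 at 0.64 (SE 0.08), XPC at 0.53 (SE 0.12) and DDB2 at -0.67 (SE 0.15), and the list's adjusted p was 0.236. Of 18 NRF2 target and antioxidant genes, 4 rose, with HMOX1, or heme oxygenase, at 1.09 (SE 0.10), and TALDO1 fell by 0.35 (SE 0.07), the median being -0.01 and the mean 0.09 (adjusted p = 0.508). Of 15 NF-kB and inflammatory genes, 4 rose and 3 fell, with VCAM1 at 1.08 (SE 0.09), RELB at 0.98 (SE 0.10) and PTGS2, or cyclooxygenase, at -1.04 (SE 0.18) (adjusted p = 0.375). Of 17 metalloproteinase and inhibitor genes, 3 rose and 5 fell, with PLAT at -1.23 (SE 0.07) and PLAU, or urokinase, at -0.72 (SE 0.08) (adjusted p = 0.505). Of 23 fibroblast matrix genes, 5 rose and 1 fell, with LUM, or lumican, at 1.07 (SE 0.17) and THBS2 at 0.63 (SE 0.11) (adjusted p = 0.483). Of 22 integrin, cadherin and adhesion genes, 3 fell and 1 rose, with ITGA2 at -0.76 (SE 0.17) and ITGA5 at -0.62 (SE 0.07) (adjusted p = 0.236). Of 23 growth factor and receptor genes, 3 rose and 1 fell, with VEGFC at -0.75 (SE 0.11) (adjusted p = 0.266). Of 11 interferon-stimulated genes, PSMB8 and IFITM1 (0.40, SE 0.09) rose (adjusted p = 0.292). The contractile list had 2 falls among 17 genes, CNN3 (-0.35, SE 0.06) and TPM4 (-0.26, SE 0.06) (adjusted p = 0.505). The apoptosis list had CFLAR rising (0.66, SE 0.15) and BID falling (-0.35, SE 0.10) among 19 genes (adjusted p = 0.638). No gene of sterol synthesis, of 12 measured, or of oxidative phosphorylation, of 27, passed (adjusted p = 0.463 and 0.514). The histone and clock lists had 7 measured genes each, with H2AC6 (0.69, SE 0.07) and CRY1 (0.98, SE 0.25) rising and H2AZ1 (-0.67, SE 0.19) and BHLHE40 (-0.88, SE 0.13) falling (adjusted p = 0.762 and 0.889). Among 8 measured markers of epithelial, endothelial and blood cells, KRT19 fell by 1.27 (SE 0.17), and the list's adjusted p was 0.670.

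The ratio of the actin control signals from the 3' and the 5' end of the message was 1.03, 1.07 and 0.999 on the treated arrays and 0.995, 0.889 and 0.946 on the mock arrays, and the GAPDH ratio, which overlapped between the groups, was between 0.779 and 0.843 on all 6.

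At 6 h, with 1 array per treatment and so no replicate check and no test, the transcripts with the highest ratios were mostly abundant ones. ACTB, the cytoplasmic actin, had a signal of 22762 on the treated array and 8634 on the mock array, a log2 ratio of 1.40, and VIM, the fibroblast intermediate filament vimentin, had 1.31. GAPDH (1.17), HMGB1 (1.16), TIMP1 (1.13), ANXA2 (1.12), FN1, or fibronectin (1.12), and EEF1A1 (1.10) were of the same kind, and after quantile normalization they and ACTB and VIM had log2 ratios of 0.16 to 0.70. ACAA2, a mitochondrial thiolase, and PEX14, a peroxisomal import factor, had 1.20 and 1.12 and stayed at 1.29 and 1.22 after quantile normalization. The lowest ratios were those of PAM (-1.76), MPDZ (-1.56), ADK, adenosine kinase (-1.44), NAA50 (-1.42), STAM2 (-1.36), PTPN13 (-1.34), F2R, the thrombin receptor (-1.34), the actin pseudogene ACTBP9 (-1.34), CCPG1 (-1.32) and RIOK3 (-1.30). Other probe sets of some of these genes disagreed, with log2 ratios of -0.62 for PEX14, 0.06 and -0.44 for PAM, 0.03 for ADK, -0.02 for STAM2, 0.09, 0.00 and -0.09 for RIOK3, -0.02 and 0.75 for HMGB1 and -0.33 to 0.93 for FN1. MPDZ kept its sign at -0.36. OGG1 had a log2 ratio of -0.07, which turned to 0.05 with median centring and with quantile normalization. Its 2 probe sets left out by the filter had -0.48 and 0.16.

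Of 11108 probe sets kept at 6 h, 42 were 2-fold or more higher and 107 were 2-fold or more lower on the treated array. Centring each array on its median moved all ratios up by 0.12 on the log2 scale and turned this split to 88 higher and 60 lower, and quantile normalization gave 15 and 68. The 328 probe sets above a signal of 8000 on either array had a median log2 ratio of 0.67, and the highest signal was 10699 on the mock array and 22762 on the treated array. On the 12 h arrays, of another type, the highest signals were 19328 to 25096, in mock and treated cells alike.

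**Figure D2:**
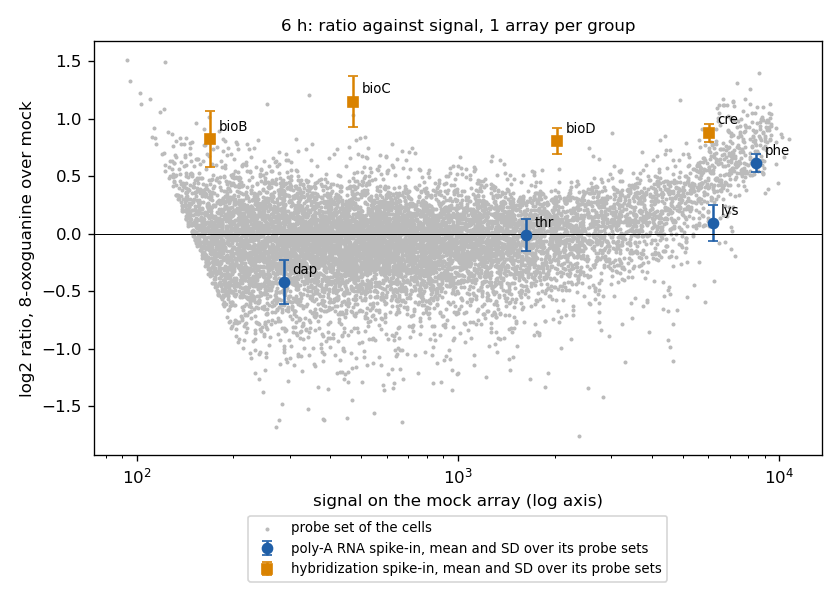
Each grey point is a probe set of the cells at 6 h, with its signal on the mock array on a log horizontal axis and the log2 ratio of treated to mock on the vertical axis, and coloured marks are the mean and SD over the probe sets of each spike-in transcript. Bright probe sets lie above 0, with a median of 0.83 above a mock signal of 8000, while the hybridization spike-ins lie between 0.81 and 1.15 at every signal.

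Of 25 gene lists measured at 6 h, 4 had medians outside the central 95% of 10000 random lists of like size and signal. Ribosomal protein genes had a median log2 ratio of 0.65 (percentile 99.9), which turned to -0.08 with quantile normalization, in the opposite tail (percentile 0.745), and all 29 were higher on the treated array, with RPS14 at 0.93 and RPL32 at 0.91. The unfolded protein and integrated stress response list had a median of 0.27 (percentile 99.7), with 21 of 27 genes higher, among them CHAC1 (0.67) and SHMT2 (0.48, its other probe sets at 0.31 and -0.02). The immediate early list had a median of 0.19 (percentile 99.7), with ZFP36, an mRNA-destabilising protein, at 1.03 and EREG, an EGF-family ligand, at -0.99. With quantile normalization these medians were 0.09 and 0.06 and lay inside the central 95%. Integrin, cadherin and adhesion genes had a median of -0.12 (percentile 0.78), with SDC2 at -0.58 (its other probe sets at 0.07 and -0.15), and the median was -0.0024 with median centring and -0.14 with quantile normalization. The ribosomal list also left the tail with the stricter filter (percentile 94.5), the immediate early list with no filter (96.3) and with the mean of a gene's probe sets (95.2), and the integrin list with that mean (10.3). The other 21 lists lay inside the central 95%, among them mitosis and G2 (0.01), DNA replication (-0.05) and base excision repair (-0.03), the last 2 above 0 with median centring (0.07 and 0.09).

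TXNIP had a log2 ratio of 0.09 at 6 h (its other probe sets 0.28 and -0.12), ID1 0.33 and ID3 0.18, against their falls at 12 h, while TRIB3 (0.41) and ASNS (0.25) lay above 0 at both, as did the median of the unfolded protein and integrated stress response list (0.27 and 0.30). With quantile normalization TRIB3 stayed at 0.43 at 6 h, while ASNS and the median of the list each became 0.09. Across 4446 probe sets kept at both times, Pearson's r of the log2 fold changes was -0.106 and Spearman's rho -0.122. This correlation is across probe sets, which are not independent replicates, and the highest absolute r among the other 9 splits of the 12 h arrays was 0.247. Of 675 probe sets called at 12 h and kept at 6 h, 300 had the same direction at 6 h, 44.4%, against 45.6% of those not called. Time, array type and the number of arrays differed together, so the difference between the times was not tested.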

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

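The tests of scaling, RNA quality, culture and spike-ins in this part were chosen after the results were seen.

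One control probe set of the lys spike-in, an added bacterial transcript that is not part of the comparisons above, was higher on all 3 treated arrays than on all 3 mock arrays at 12 h. Its signal was 1955 ± 60.8 in mock and 2344 ± 34.4 in treated cells (SD, n = 3), a log2 fold change of 0.26 in a limma fit that included the controls. Of 29 measured genes of the immediate early list, 9 fell, 2 rose and 18 did not pass at 12 h, and its camera adjusted p of 0.0450 was 0.170 with an estimated correlation, 0.0582 with median centring and 0.0569 with quantile normalization. Its median log2 ratio at 6 h was 0.19, which became 0.06, inside the central 95%, with quantile normalization. The difference between the times was not tested.

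The 12 h calls could in part come from how the arrays were scaled, from RNA quality or from the cultures. After quantile normalization 96.3% of the called probe sets stayed past the threshold with the same sign, which argues against scaling as the whole source. The highest 3'/5' ratio of the actin and GAPDH controls was 1.07, but the actin ratios of the groups did not overlap (the GAPDH ratios did), so RNA quality stays open. Of the called probe sets kept at 6 h, 44.4% had the same direction in the separate 6 h arrays, against 45.6% of those not called, and since treatment and culture go together at 12 h, an effect of the compound and another difference between the cultures cannot be told apart. The 10 splits of the 6 arrays are too few for a share under 0.05: the real split, 1 of them, gave 695 probe sets (1508 at an unadjusted p under 0.05 in limma) and 10 lists, and the highest of the others 0 probe sets (339 in the same way) and 5 lists.

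The rise of bright transcripts at 6 h could come from a compressed top of the signal range on the mock array or from a rise of abundant mRNAs. The phe spike-in, bright on the mock array at 8460, had a log2 ratio of 0.61, and thr, at 1632, had -0.01, which go with compression. Against it, lys, at 6194, had 0.09 where cell probe sets of like signal had 0.48. Dap had -0.42 where cell probe sets of like signal had -0.05, but at 288 it is far from the top of the range. The hybridization spike-ins had 0.82 (bioB), 1.15 (bioC), 0.81 (bioD) and 0.88 (cre), whether dim or bright. A shift that does not depend on signal, with amounts not known, speaks neither for nor against compression. In all, 2 of the 8 transcripts lay within 0.3 of cell probe sets of like signal. Those of the probe sets above 8000 at 6 h that were also on the 12 h arrays and kept there had a median log2 fold change of 0.0851 at 12 h. This does not exclude a rise that had ended. The highest signals of the 12 h arrays, 19328 to 25096, were near that of the treated 6 h array (22762) and above that of the mock (10699). This goes with compression, but the array types differ. One cre probe set went between, with 10557 to 11737 at 12 h, 7743 on the mock and 14574 on the treated 6 h array. Both explanations stay open, since the amounts of spike-in on each array are not known and there was 1 array per treatment.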

How the results depend on the processing

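The limits of 1.5-fold and of a signal of 4000 were chosen after seeing the data. The count of 695 probe sets at 12 h lay between 484 (no intensity trend) and 731 (quantile normalization) under the other planned settings that kept all arrays, and was 252 with a 1.5-fold minimum, which requires more by construction. Leaving out 1 array gave 371 to 649, with fewer samples. The replicate numbers were shared numbers only, with correlations of same-numbered arrays of 0.076, -0.149 and -0.050, and not every array correlated best with its own number. With the replicate block 513 probe sets passed, 492 of them shared with the 695. The 10 lists became 6 with the stricter filter, which tests fewer genes, 2 with an estimated correlation and 19 with fry, which asks another question. The estimated correlation was above the preset 0.01 in the glycolysis, stress response and ribosomal lists (0.095, 0.116 and 0.169). In the heat shock, base excision repair, TGF-beta, immediate early and purine lists it was below 0.01, from -0.035 to -0.0023. A higher correlation therefore does not account for the calls that these last lists lost. The mitosis and DNA replication lists were also below 0.01 (-0.023 and -0.0079). Their camera adjusted p still rose from 6.26e-13 and 1.36e-09 to 0.0275 and 0.0280. The setting thus raised adjusted p even without a higher correlation. A call lost under it is therefore no sign by itself of correlated genes in a list or family. Leaving out 1 array gave 7 to 10 lists. At 6 h the 149 probe sets at 2-fold or more became 83 with quantile normalization, 3167 with no filter, which adds dim probe sets, 67 with the stricter filter and 118 with signals below 4000 only. Of the 4 lists, 1 stayed in its tail with quantile normalization (ribosomal proteins crossed to the other), 2 with the mean of a gene's probe sets, and 3 with no filter and with the stricter filter. The correlation of -0.106 between the times became -0.030 with no filter, and -0.152 to -0.070 without 1 array. For these changes the cause was not tested unless named.

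Some values changed sign. OGG1 at 12 h was 0.14 without 8-oxoguanine replicate 1 and 0.0013 without mock replicate 3, and lay between -0.20 and 0.14 over the arrays left out. The clock list, never past the threshold in camera, turned with no filter (adjusted p = 0.881), the replicate block (0.970) and without 8-oxoguanine replicate 3 (0.653), with adjusted p up to 0.989 over the arrays left out. The histone list turned with no filter (adjusted p = 0.990). Ribosomal proteins at 6 h turned to a median of -0.0824 with quantile normalization. The cause was not tested. Of the comparisons of 102 named genes at 12 h with their alternatives, 1110 kept direction and side of the threshold, 173 lost the call and 4 gained it. For the 26 lists these were 343, 31 and 9. Dim probe sets limit the values, as no detection calls give signal over background.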

Other observations

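The gene families in this part were chosen after the 12 h results were seen. Their p-values come from the same arrays, so they describe the families and are no independent test of them. A set of 5 families was tested first, and 4 of them had adjusted p under the threshold with an estimated correlation. Families that had been considered but not run were then added, which made 8, and with all 8 in the adjustment no family passes with an estimated correlation.

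Amino acid transporter genes had 7 rises among 14 measured at 12 h and no fall, with SLC7A2 at 0.94 (SE 0.10), SLC7A5, a large neutral amino acid carrier, at 0.89 (SE 0.07) and SLC1A4 at 0.78 (SE 0.10) (camera adjusted p = 0.000115, and adjusted p = 0.0513 with an estimated correlation). Cytosolic aminoacyl-tRNA synthetases had 6 rises among 14, with WARS1 at 0.77 (SE 0.08) (0.00181, and 0.0647 with an estimated correlation). Lysosomal genes had 7 rises among 23, with the cathepsins CTSO and CTSK at 0.64 (SE 0.09) and 0.63 (SE 0.09) (0.000123, and 0.0513 with an estimated correlation). Proteasome subunits had 7 falls among 28, with PSMD5 at -0.44 (SE 0.12) and PSMD14 at -0.41 (SE 0.07) (8.89e-06, and 0.0791 with an estimated correlation). PSMB8, a proteasome subunit among the 10 largest rises (1.42, SE 0.36), was not in this family. Endoplasmic reticulum chaperones had 3 falls among 8, SDF2L1 (-0.75, SE 0.13), MANF (-0.70, SE 0.11) and HYOU1 (-0.56, SE 0.10) (0.0130, and 0.0831 with an estimated correlation). Signal recognition, translocon, COPII and KDEL receptor genes had 6 falls and 1 rise among 24 (0.0449, and 0.110 with an estimated correlation), EIF3 subunits 3 rises among 11 (0.0449, and 0.110), and vacuolar ATPase subunits no call among 11 (0.837, and 0.850). The pattern that picked the signal recognition family first also took SSRP1, which is not a member, and this was corrected after the values were seen (25 genes, 0.0449 before). Leaving out the KDEL receptors as well, also tried after the values were seen, gave 5 falls and 1 rise among 22 and camera adjusted p = 0.113. In camera 5 of the 8 families then passed instead of 7, as the EIF3 subunits lost their call too. The calls of the signal recognition family and of EIF3 therefore depend on how the signal recognition family is drawn.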
